A study of Mus musculus with 6 samples.

How the data were processed

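Poly(A) RNA from mouse hearts at embryonic day 12.5 (E12.5) was sequenced in 6 libraries, 3 from control embryos and 3 from embryos labelled as a Trim28 conditional knockout (CKO). Per the labels' protocols, RNA was extracted with a micro-scale column kit, 500 ng of total RNA entered each library, and libraries were made with the NEBNext Ultra RNA kit for an Illumina HiSeq instrument. Groups and replicate numbers were taken from the sample titles. The genotype label of the CKO samples reads knockdown where the titles read CKO. The titles were followed here. The Cre driver, the exons removed, the number of hearts in a library, the aligner, the counting program and the gene annotation are not given in the sources used here. The genome build was mm10, per the submitters' processing notes. No label says that the libraries came from separate animals or separate pools, so the p-values measure the spread between these samples.

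The deposited table holds raw read counts per gene symbol for the 6 libraries, which are named as raw counts per the labels. The values were whole numbers, and the 6 columns summed to between 34400841 and 39763233 counts. The table had 30619 rows, none of them at 0 in every library and none of them without a gene name. A statistics program had altered 2017 symbols (a hyphen turned into a point, for example), and these were restored where exactly 1 symbol of the GENCODE M21 mouse annotation gave the deposited form. A further 24 rows carried calendar dates in place of symbols, 4 of which shared a name with another row. These were kept in library sizes and not named. Positions and gene classes came from GENCODE M21, on the mm10 build, for 30151 rows that matched 1 gene. The other 468 rows did not match a single gene. It is not given whether the counting used strand or how reads shared by several genes were treated, so the values of overlapping genes, antisense genes and near-identical copies are uncertain.

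Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr at its default minimum count of 10 and total of 15, which left 17557 genes and removed 0.0756% of all counts. Libraries were scaled with TMM factors, dispersions were estimated robustly, and a quasi-likelihood model with group as its only term was fitted (glmQLFit, robust, and glmQLFTest, two-sided). P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were the fold change divided by the square root of the F statistic. CPM (counts scaled to the library size) used TMM-scaled library sizes. Unless another test is named, each adjusted p of a gene comes from this edgeR test. Log2 fold changes are CKO over control throughout, and n is 3 per group.

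Before the data were examined, 35 gene lists were fixed for chamber myocardium, cardiac function, TRIM28-linked chromatin, stress, metabolism, sex and other cell types. Some lists share genes, so their tests are not independent. The 34 lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. The test was repeated with a correlation estimated for each list, and with fry, which tests whether a list's genes move, on balance, one way without comparing them with other genes. A mixed form of fry tested whether a list's genes changed in either direction. The genes to be named were fixed by a rule at the same time. They were Trim28, the 8 called genes with the largest rise and the 8 with the largest fall among genes with a mean log2 CPM of at least 1 and no overlap between the groups, leaving out predicted, unnamed and sex-linked genes, and up to 4 members per list with the smallest adjusted p (up to 2 where no member was called). All tested members of the trabecular and compact myocardium lists could also be named.

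The pipeline was tested on simulated counts drawn from the means, dispersions and library sizes of this comparison, of which 17167 genes passed the filter. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery below that level was not tested. Of 50 genes changed 1.2-fold it recovered 6%, of 50 changed 1.5-fold 76%, of 50 changed 2-fold 84% and of 50 changed 4-fold 94%. Of all 137 simulated calls, 5.11% were genes that had not been changed. With no gene changed, it made 0 calls.

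The alternatives fixed beforehand were RLE, upper-quartile or no scaling factors, DESeq2 1.42.0, limma-voom, edgeR's legacy and non-robust fits, no filter or a filter of at least 1 CPM in 3 libraries, the replicate number as a block, leaving out each library in turn, removing erythroid and mitochondrially encoded genes, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and a test against a fold of 1.2 (glmTreat). A covariate for Y-linked expression, a covariate for the share of a ribosomal RNA row and the removal of ribosomal RNA rows were added after seeing the data. Replicate libraries were compared for duplicates by a chi-square statistic of their counts. Within groups it was 9.87 to 18.7 per degree of freedom, far above the value near 1 of repeated sampling, and no library was treated as a copy.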

Results

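RNA from E12.5 mouse hearts was profiled to compare control embryos with embryos carrying a conditional knockout of Trim28. TRIM28, also called KAP1, is a co-repressor that is brought to DNA by zinc finger proteins and recruits heterochromatin factors. The series concerns the part of TRIM28 in ventricular chamber formation, namely trabeculation, the growth of muscular ridges into the lumen, and compaction, the thickening of the outer wall. Each group had 3 libraries of mixed cardiac cells. The control libraries held 39702929, 38449175 and 36854002 counts, and the CKO libraries 37024246, 34400841 and 39763233. Between 23736 and 24725 genes had at least 1 count in a library.

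Trim28 (ENSMUSG00000005566.14, chromosome 7, 12999114 to 13031035, plus strand) was measured at 305, 391 and 443 CPM in control replicates 1, 2 and 3 and at 172, 314 and 165 CPM in the libraries labelled CKO 1, 2 and 3. The means were 380 ± 69.7 CPM in controls and 217 ± 84.1 CPM in CKO (SD, n = 3 each). The log2 fold change was -0.81 with an SE of 0.34, and the edgeR quasi-likelihood test did not call it (adjusted p = 0.34). It was called by limma-voom (adjusted p = 0.0165) and by the non-robust edgeR fit (adjusted p = 0.0194). The library labelled CKO 2 lay inside the range of the controls, and without it the log2 fold change was -1.17 (adjusted p = 0.0763). Counts over the whole gene also include reads from exons that a deletion leaves in place, and the exons removed are not given in the sources used here, so the level does not measure the share of cells that lost the protein. This gene does not bear out the label of the library labelled CKO 2, and each direction given for the CKO group rests on the labels.

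**Figure D1:**
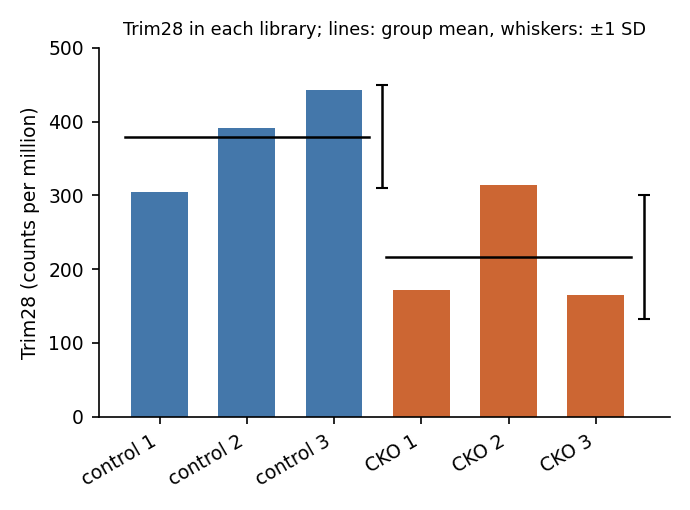
Trim28 level in CPM (vertical axis) in each of the 6 libraries (bars), with the group mean (line) and ±1 SD (whisker). The libraries labelled CKO 1 and CKO 3, at 172 and 165 CPM, lie below each control, and the library labelled CKO 2, at 314 CPM, lies above the lowest control, at 305 CPM.

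Hearts labelled CKO expressed 532 genes at a higher and 188 at a lower level than controls among 17557 tested. Most changes were modest. The median log2 fold change was 0.47 among the higher and -0.32 among the lower genes, and 94 of the higher but 7 of the lower genes changed by at least 1 on the log2 scale. The largest rises among genes named by rule were those of Kcnj6 (chromosome 16, 94748636 to 94997701), a potassium channel gene, with a log2 fold change of 2.33 (SE 0.24, adjusted p = 1.8e-05), from 1.28 ± 0.0276 to 6.39 ± 1.42 CPM (SD, n = 3), and Xirp2 (chromosome 2, 67446002 to 67526614), which encodes an actin-binding protein of striated muscle, with a log2 fold change of 1.98 (SE 0.24, adjusted p = 8.1e-05). They were followed by Adamts18 (1.96), Tnnt3 (1.89), which encodes the fast skeletal troponin T, Tmem215 (1.84), Galnt15 (1.79), the homeobox gene Hoxa5 (1.77) and the collagen gene Col22a1 (1.72). Kcnj6 and Tnnt3 overlap Gm41505 and Prr33, which were also called, so their reads cannot be told apart without strand. The largest falls were those of B3gnt3 (-1.07), Btn1a1 (-1.04), Papss2 (-1.01), Mybpc1 (-0.91), Zfp366 (-0.88), Oprd1 (-0.84), Fmn2 (-0.81) and Plppr1 (-0.73). Of these 8, Papss2 and Mybpc1 were called in 5 of the 6 fits that left out 1 library and the others in 1 or 2 (adjusted p up to 0.217), as was Hoxa5 in 2 (adjusted p up to 0.0936) among the rises; the other 7 rises were called in all 6. With a covariate for the ribosomal RNA share, Kcnj6 and Tnnt3 were called and the other 14 of these genes were not (adjusted p up to 0.663). With a covariate for Y-linked expression, Adamts18, B3gnt3, Btn1a1, Zfp366, Oprd1, Fmn2 and Plppr1 were not called (adjusted p from 0.0735 to 0.39). Papss2, which makes the sulfate donor of the cell, fell from 60.5 ± 9.69 to 30.1 ± 4.25 CPM (SD, n = 3, adjusted p = 0.0031).

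The control and CKO values did not overlap in 719 of the 720 called genes. Groups of 3 and 3 part in this way in 22.1% of all tested genes, and in 10% by chance. At an unadjusted p under 0.05 there were 3126 genes. The counts moved with single libraries. Higher and lower calls numbered 255 and 67 without control replicate 1, 312 and 48 without control replicate 2, 256 and 45 without control replicate 3, and 269 and 39 without CKO replicate 3, while 407 and 139 were called without CKO replicate 1 and 1012 and 540 without the library labelled CKO 2. Of the 720 calls, 204 were made in each of these 6 fits, and no called gene turned its direction. A ribosomal RNA share was higher in each CKO library than in each control. A call lost with this share as a covariate therefore does not tell the share from the group. Sex-linked transcripts varied between and within the groups. A ribosomal RNA row (CT010467.1) took 0.522%, 0.222% and 0.127% of the counts in control replicates 1, 2 and 3 and 0.79%, 0.672% and 0.563% in CKO replicates 1, 2 and 3, and with its log2 share as a covariate 53 higher and 3 lower genes were called, among them 16 of the 80 called genes named by rule. Xist, which is transcribed from the inactive X chromosome of females, had 24633, 36330 and 17569 counts in the controls and 15232, 7 and 4 in CKO, and the Y-linked gene Ddx3y had 1153, 0 and 1604 counts in the controls and 1382, 2597 and 2626 in CKO. Control replicates 1 and 3 and CKO replicate 1 thus held both transcripts, which points to RNA of more than 1 embryo, of both sexes, in each. With Y-linked expression as a covariate, 320 higher and 63 lower genes were called, among them 44 of these 80.

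Markers of the trabecular and the compact layer did not move as groups in the main camera test, though the trabecular list was called on DESeq2 statistics. Of 12 tested trabecular genes, 2 were higher and none lower, and the 2 were the natriuretic peptide genes Nppb, which rose from 114 ± 3.29 to 294 ± 45.4 CPM (SD, n = 3, log2 fold change 1.36, SE 0.10, adjusted p = 0.00015), and Nppa (0.38, SE 0.09, adjusted p = 0.038). Nppb was called in each fit that left out 1 library, Nppa in 2 of these 6 (adjusted p up to 0.27). The other trabecular genes were not called, among them Irx3 (0.25), Gja5 (-0.43, SE 0.25), Etv1 (-0.21), Bmp10 (0.13, SE 0.22), Sema3a (-0.15) and Cited1 (0.00, SE 0.08). Adjusted over the list alone, 3 were higher. The camera test gave an adjusted p of 0.41, and 0.0018 on DESeq2 statistics. Of 10 compact-layer genes, 1 was lower and none higher. This was Mycn, which promotes growth of the compact myocardium, at 61.3 ± 3.21 CPM in controls and 40.4 ± 7.95 CPM in CKO (SD, n = 3, log2 fold change -0.60, SE 0.12, adjusted p = 0.017), and it kept its call in 3 of the 6 fits that left out 1 library (adjusted p up to 0.082). Hey2, a transcription factor of the compact layer, had a log2 fold change of -0.27 (SE 0.08, adjusted p = 0.066), and Prdm16 (-0.11), Tbx20 (0.11), Ccnd1 (-0.03) and Tgfb2 (0.00) were not called. Adjusted over the list alone, 1 was higher and 2 were lower, and the list was not called (camera adjusted p = 0.76). The mixed form of fry, which takes changes in either direction, called both the trabecular (adjusted p = 0.00025) and the compact list (adjusted p = 0.0098).

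Among 25 genes of trabeculation signalling, which covers the Notch, neuregulin, BMP and angiopoietin pathways, 1 was called, also adjusted over the list alone. This was Tek, the angiopoietin receptor of endothelium, with a log2 fold change of -0.36 (SE 0.06, adjusted p = 0.002). Tek was not called with the ribosomal RNA covariate (adjusted p = 0.254). Dll4 (-0.30, adjusted p = 0.079) and Notch1 (-0.22, adjusted p = 0.11) did not pass. The list was not called (camera adjusted p = 0.28), but was called lower without the library labelled CKO 2 (adjusted p = 0.0245). Of 14 genes of the cardiac jelly, the matrix between myocardium and endocardium, Fbln2 alone was lower (-0.30, SE 0.07, adjusted p = 0.017, list alone 1 lower, camera adjusted p = 0.57), and Vcan was at -0.26 (adjusted p = 0.22). Of 24 cardiac transcription factors, Hand2 (-0.23, adjusted p = 0.026) and Foxp1 (-0.24, adjusted p = 0.032) were lower and none was higher, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.71). Fbln2, Hand2 and Foxp1 each lost their call in at least 4 of the 6 fits that left out 1 library.

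Many glycolytic and hypoxia-responsive genes were higher. Of 28 tested, 17 were higher and none lower, and 22 were higher adjusted over the list alone, with a median log2 fold change of 0.29. Slc16a3, the lactate exporter, rose from 236 ± 7.08 to 439 ± 28.8 CPM (SD, n = 3, log2 fold change 0.90, SE 0.06, adjusted p = 3.1e-08). Hk2, which encodes hexokinase 2, had a log2 fold change of 0.73 (SE 0.07, adjusted p = 3.3e-05), Bnip3, a hypoxia-induced mitophagy gene, one of 0.56 (SE 0.06, adjusted p = 3.6e-05), and the phosphofructokinase gene Pfkp one of 0.45 (SE 0.05, adjusted p = 9.1e-05). These 4 genes kept their call without each library in turn and with either added covariate. The camera test gave an adjusted p of 1.8e-13, and an adjusted p of 0.23 with an estimated correlation. The fry test gave an adjusted p of 0.012. Of the lists given below that camera called, fry also called the macrophage (adjusted p = 0.0124), smooth muscle (0.0124), immediate-early (0.0147) and cell cycle lists (0.0269). It did not call the sarcomere (adjusted p = 0.147), atrial (0.0954), ventricular (0.406), endothelial (0.14) or erythroid list (0.495). Nor did it call the p53 target (adjusted p = 0.0954), integrated stress response (0.133) or interferon list (0.329).

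Some genes of immediate-early and stress responses were higher. Of 20 immediate-early and heat shock genes, 4 were higher and none lower (10 higher adjusted over the list alone, camera adjusted p = 5.0e-06, adjusted p = 0.23 with an estimated correlation). Egr1, a serum-induced transcription factor, rose by 1.18 (SE 0.09, adjusted p = 3.0e-07) and Ier3 by 0.93 (SE 0.09, adjusted p = 8.8e-06) on the log2 scale. Zfp36 (0.57) and Hspa1b (0.94), which has a near-identical copy and was called in 2 of the 6 fits that left out 1 library (adjusted p up to 0.136), were the others. Of 26 p53 targets, 5 were higher and none lower (11 higher adjusted over the list alone, camera adjusted p = 5.3e-06, adjusted p = 0.42 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose by 0.80 (SE 0.13, adjusted p = 0.0069) and was called without each library in turn but not with the ribosomal RNA covariate (adjusted p = 0.32), whereas Btg2 (0.37), Zmat3 (0.30) and Gdf15 (1.52) were called in 3, 4 and 2 of these fits. Of 24 genes of the integrated stress response, 3 were higher, namely Vldlr (0.46), Gdf15 and Sesn2 (0.62, called in 2 of these fits), with 5 adjusted over the list alone (camera adjusted p = 0.0037, adjusted p = 0.63 with an estimated correlation). This list was not called without CKO replicate 1 (adjusted p = 0.0779) or with the ribosomal RNA covariate (adjusted p = 0.0757). Its members Gdf15 and Sesn2 also stand in the p53 target list. Of 37 cell cycle genes, 4 were lower and none higher (12 lower adjusted over the list alone, median log2 fold change -0.11, camera adjusted p = 1.4e-06, adjusted p = 0.23 with an estimated correlation). They were the mitotic genes Kif11 (-0.23, SE 0.05) and Nusap1 (-0.24, SE 0.06) and the replication genes Mcm6 (-0.20, SE 0.05) and Mcm4 (-0.19, SE 0.05). Each was called in at most 2 of the 6 fits that left out 1 library, while the list was called in all 6. Of 32 genes of fatty acid and mitochondrial energy metabolism, 2 creatine kinase genes were higher, Ckb (0.59, SE 0.08, adjusted p = 0.00068) and Ckmt2 (0.70, SE 0.17, adjusted p = 0.021, called in 2 of the 6 fits that left out 1 library), with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.31, 0.0024 with the Y-linked covariate).

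**Figure D2:**
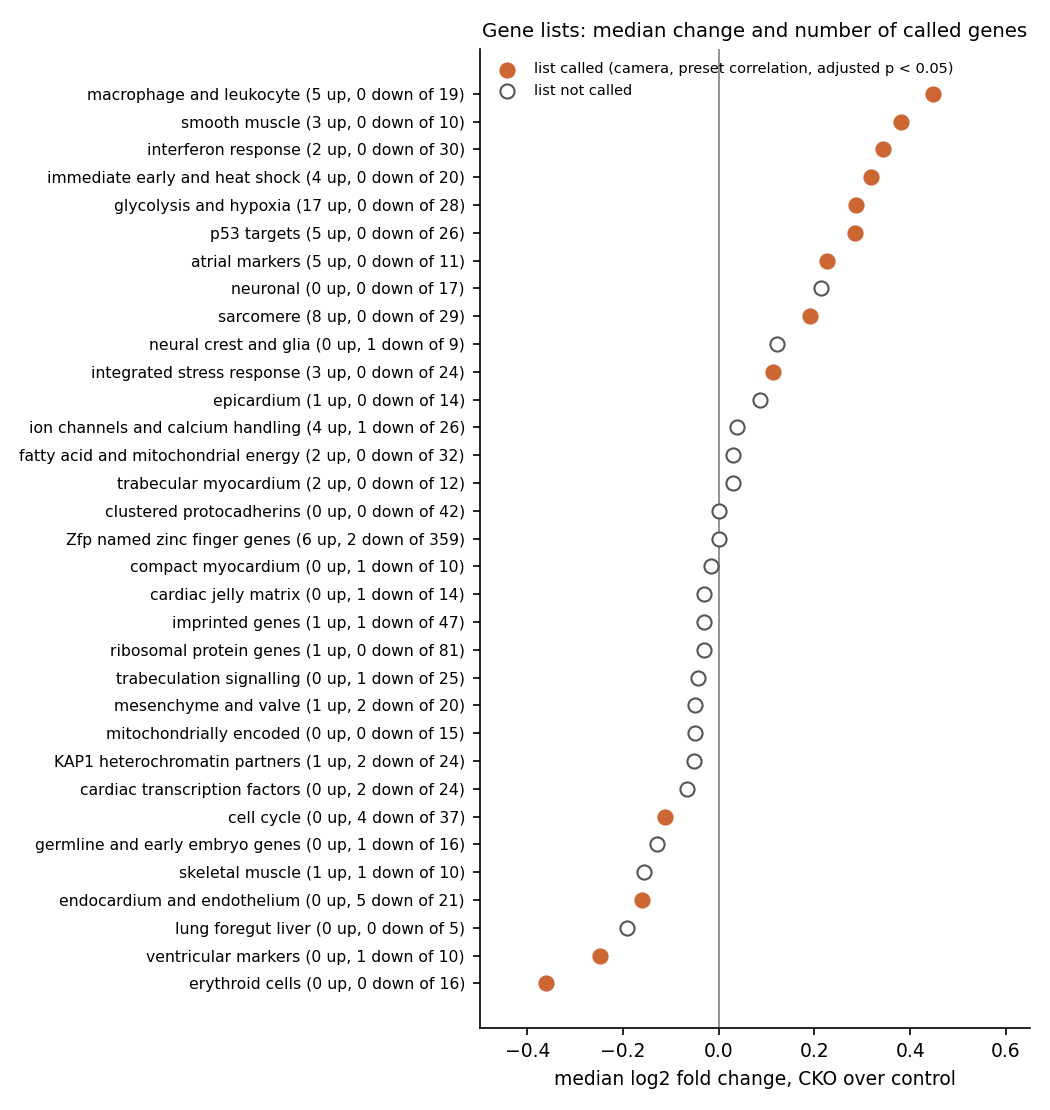
Median log2 fold change, CKO over control (horizontal axis), of each tested gene list other than the Y-linked list (rows), with the number of its members called higher and lower beside its name. Filled points are lists called by camera with the preset correlation, from the macrophage and leukocyte list at 0.45 to the erythroid list at -0.36; open points were not called.

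Contractile and atrial genes were higher in part. Of 29 sarcomere genes, 8 were higher and none lower (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.3e-06, adjusted p = 0.70 with an estimated correlation). Besides Xirp2, they included the atrial myosin light chain gene Myl7, which rose from 820 ± 68.8 to 1180.5 ± 131 CPM (SD, n = 3, log2 fold change 0.53, SE 0.08, adjusted p = 0.0052), Myom2 (0.92, SE 0.17, adjusted p = 0.0053) and the alpha myosin heavy chain gene Myh6 (0.33, SE 0.07, adjusted p = 0.01). Myh6 is similar in sequence to Myh7, overlaps a called predicted gene and was called in 2 of the 6 fits that left out 1 library. Of 11 atrial markers, 5 were higher and none lower (6 higher adjusted over the list alone). Kcna5, an atrial potassium channel gene, rose by 0.84 (SE 0.11, adjusted p = 0.00018), Sln, which encodes the calcium pump inhibitor sarcolipin, by 0.95 (SE 0.16, adjusted p = 0.0027) and Myl4 by 0.23 (SE 0.06, adjusted p = 0.023) on the log2 scale, Myl4 with a call in 1 of these fits and the other 2 in all 6, though Sln was not called with the ribosomal RNA covariate (adjusted p = 0.14). The atrial list was called (camera adjusted p = 0.0036, adjusted p = 0.42 with an estimated correlation) but not without the library labelled CKO 2 (adjusted p = 0.0507). Of 10 ventricular markers, Mpped2 alone was lower (-0.33, SE 0.07, adjusted p = 0.01, called in 3 of these fits), none was higher and 3 were lower adjusted over the list alone. Myh7, the beta myosin heavy chain gene, was at -0.23 (SE 0.08, adjusted p = 0.14). The ventricular list was called lower (camera adjusted p = 0.031, adjusted p = 0.80 with an estimated correlation), but not without control replicate 1 (adjusted p = 0.149), control replicate 2 (0.149), CKO replicate 1 (0.108) or CKO replicate 3 (0.0984), nor with the Y-linked covariate (0.265).

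Of 26 genes of ion channels and calcium handling, 4 were higher, among them the pacemaker channel gene Hcn4 (0.37, SE 0.08, adjusted p = 0.017), and 1 was lower, the phospholamban gene Pln (-0.51, SE 0.09, adjusted p = 0.012). Hcn4 was called in 2 and Pln in 3 of the 6 fits that left out 1 library (adjusted p up to 0.0986). The list, with 8 higher and 5 lower adjusted over it alone, was not called (camera adjusted p = 0.61). Of 10 smooth muscle genes, 3 were higher and none lower (6 higher adjusted over the list alone), and all 10 had a positive log2 fold change. Acta2, the smooth muscle actin gene, which embryonic heart muscle also expresses, rose from 1208 ± 22.3 to 1891 ± 248 CPM (SD, n = 3, log2 fold change 0.65, SE 0.08, adjusted p = 0.00064). Myh11 rose by 1.61 (SE 0.24, adjusted p = 0.0031) and Cnn1 by 0.47 (SE 0.08, adjusted p = 0.0055), and these 3 kept their call without each library in turn, whereas with the ribosomal RNA covariate Myh11 (adjusted p = 0.30) and Cnn1 (adjusted p = 0.31) were not called. The list was called (camera adjusted p = 5.3e-06, adjusted p = 0.20 with an estimated correlation). Of 10 skeletal muscle genes, Tnnt3 was higher and Tnni2, the fast troponin I gene, was lower (-0.60, SE 0.12, adjusted p = 0.0045), with 2 higher and 1 lower adjusted over the list alone. This list was not called (camera adjusted p = 0.83), and its median (-0.16) and its mean (0.13) differed in sign.

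**Figure D3:**
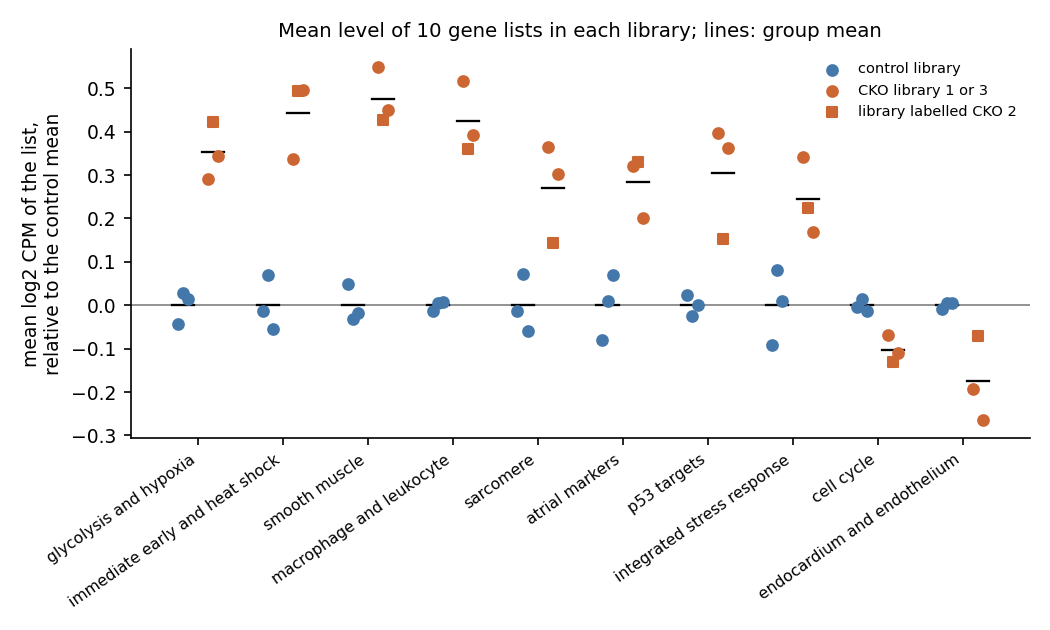
Mean log2 CPM of the members of 10 gene lists in each library, relative to the mean of the 3 controls (vertical axis), with lines at the group means. In each of the 10 lists the 3 CKO libraries lie on one side of the 3 controls. The library labelled CKO 2 (square) lies nearest to the control mean of the 3 in 5 lists, namely the smooth muscle, macrophage, sarcomere, p53 target and endothelial lists. The 10 were chosen from the 13 called lists. Of the called lists not shown, the groups overlap in the ventricular and erythroid lists but not in the interferon list.

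Markers of other cardiac cell types moved in different directions. Of 21 endocardial and endothelial genes, 5 were lower and none higher, and 20 had a negative log2 fold change (10 lower adjusted over the list alone). Besides Tek they included Cdh5, the endothelial cadherin gene (-0.30, SE 0.06, adjusted p = 0.0084), Plvap (-0.35, SE 0.07, adjusted p = 0.0098) and Ramp2 (-0.28, SE 0.06, adjusted p = 0.014), called in 3, 3 and 4 of the 6 fits that left out 1 library (adjusted p up to 0.111). The list was called (camera adjusted p = 5.0e-06, adjusted p = 0.63 with an estimated correlation). Of 19 macrophage and leukocyte genes, 5 were higher and none lower (9 higher adjusted over the list alone, camera adjusted p = 2.2e-07, adjusted p = 0.20 with an estimated correlation). Lyz2, the macrophage lysozyme gene, which has a close copy, rose from 35.1 ± 5.6 to 56.4 ± 4.1 CPM (SD, n = 3, log2 fold change 0.69, SE 0.10, adjusted p = 0.00088), and the complement genes C1qc (0.62, SE 0.13) and C1qa (0.67, SE 0.15) and Laptm5 (0.45, SE 0.11) were also higher. Lyz2 kept its call without each library in turn, and C1qc, C1qa and Laptm5 in 4, 2 and 2 of these 6 fits (adjusted p up to 0.146). With the ribosomal RNA covariate none of these 4 was called (adjusted p from 0.127 to 0.633). Of 16 erythroid genes, none was called, also adjusted over the list alone, and 14 had a negative log2 fold change. Klf1 was at -0.93 (SE 0.36, adjusted p = 0.17). The list was called lower (camera adjusted p = 0.037, adjusted p = 0.80 with an estimated correlation), but without control replicate 1, 2, CKO replicate 1, 2 or 3 its adjusted p was 0.256, 0.0983, 0.108, 0.051 and 0.124.

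Of 14 epicardial genes, the keratin gene Krt19 alone was called, higher by 0.59 (SE 0.09, adjusted p = 0.0017, list alone 1 higher, camera adjusted p = 0.57). Krt19 was not called with the ribosomal RNA covariate (adjusted p = 0.252). Of 20 genes of mesenchyme and valves, the homeobox gene Prrx2 was higher (0.48, SE 0.08, adjusted p = 0.001) and the matrix genes Postn (-0.29, SE 0.06, adjusted p = 0.016) and Tgfbi (-0.23, SE 0.05, adjusted p = 0.017) were lower, as they were adjusted over the list alone (camera adjusted p = 0.28). Prrx2 was called in all 6 fits that left out 1 library, Postn and Tgfbi in 3 (adjusted p up to 0.121), and none of the 3 with the ribosomal RNA covariate (adjusted p from 0.219 to 0.82). None of 17 neuronal genes was called (camera adjusted p = 0.15), and the list was called higher without control replicate 1 (adjusted p = 0.0254). Of 9 neural crest and glial genes, Erbb3 alone was lower (-0.35, SE 0.10, adjusted p = 0.046, called in 2 of these fits, list alone 1 lower, camera adjusted p = 0.94). The median of that list was 0.12 while the camera direction was down. None of 5 lung, foregut and liver genes was called (camera adjusted p = 0.63), and none of 15 mitochondrially encoded genes (camera adjusted p = 0.70). Of 81 ribosomal protein genes, Rps4l, a gene with near-identical relatives, was higher (0.42, SE 0.09, adjusted p = 0.021, called in 3 of these fits, list alone 1 higher, camera adjusted p = 0.11). That list was called lower in 6 of 23 alternatives, among them those without control replicate 3 (adjusted p = 0.0016), without CKO replicate 1 (adjusted p = 9.5e-05), with the ribosomal RNA covariate (adjusted p = 1.7e-08) and with DESeq2 (adjusted p = 0.0335).

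**Figure D4:**
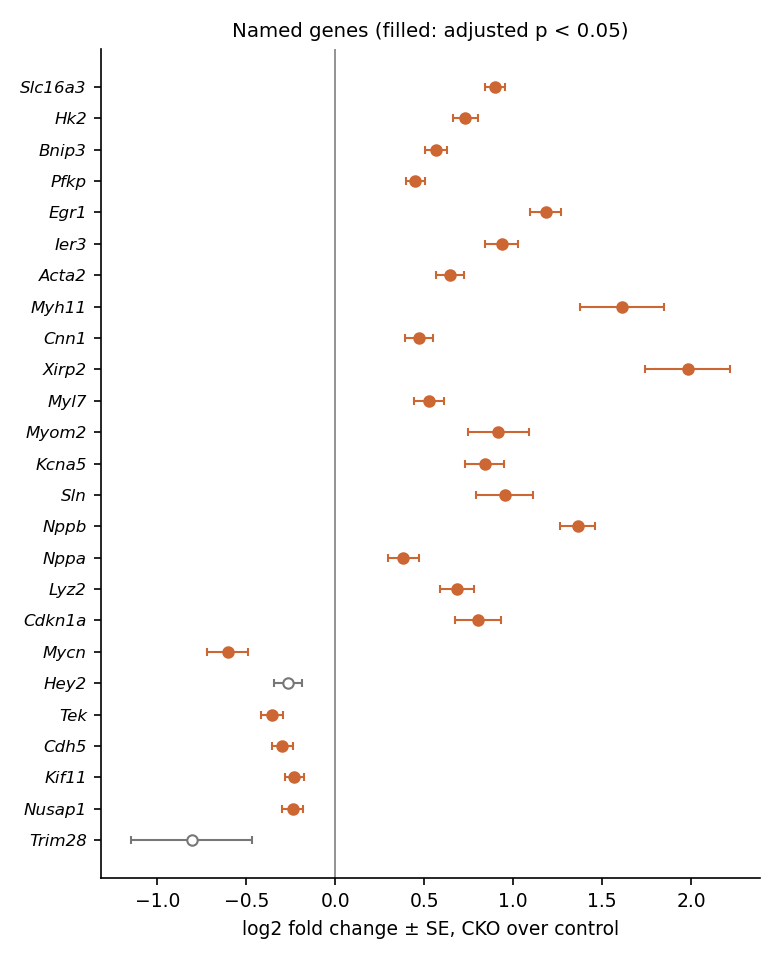
Log2 fold change, CKO over control, with its SE (horizontal axis) for a selection of the genes named by list and for Trim28 (rows). Filled points passed an adjusted p of 0.05; those shown run from Xirp2 at 1.98 to Mycn at -0.60; Hey2 at -0.27 and Trim28 at -0.81 are open.

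In the lists fixed for gene classes tied to TRIM28 repression, few members were called. Genes such as Znf41-ps, called higher on chromosome 4, lay outside the Zfp list because of their symbols. Of 359 genes with a Zfp symbol, most of which encode zinc finger proteins, 6 were higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.68). The higher genes included Zfp110 (0.75, SE 0.10, adjusted p = 0.00088), Zfp469 (0.67, SE 0.10, adjusted p = 0.00055), Zfp568 (0.40, SE 0.07, adjusted p = 0.0035) and Zfp36, which encodes an RNA-binding protein. With the ribosomal RNA covariate none of these 4 was called (adjusted p from 0.133 to 0.346). With the Y-linked covariate Zfp568 (adjusted p = 0.106) and Zfp36 (adjusted p = 0.0784) were not called. Of 24 heterochromatin partners of TRIM28, Uhrf1 (-0.28, SE 0.05, adjusted p = 0.0038) and Atf7ip (-0.26, SE 0.07, adjusted p = 0.034) were lower and Zfp57, a guardian of imprints, was higher (0.28, SE 0.08, adjusted p = 0.039), with 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.41). Uhrf1 was called in all 6 fits that left out 1 library but not with the Y-linked (adjusted p = 0.1) or the ribosomal RNA covariate (adjusted p = 0.30), Atf7ip in 1 of these fits and Zfp57 in 2 (adjusted p up to 0.248), and Zfp57 was at 0.14 with the Y-linked covariate (adjusted p = 0.54) and not called by limma-voom or without scaling factors. Of 47 imprinted genes, Mirg, a noncoding gene of the Dlk1 and Meg3 domain, was higher (0.82, SE 0.13, adjusted p = 0.0011) and H19 was lower (-0.18, SE 0.05, adjusted p = 0.03, called in 2 of these fits). Neither Mirg (adjusted p = 0.403) nor H19 (adjusted p = 0.408) was called with the ribosomal RNA covariate. Meg3 itself was at 0.72 (SE 0.14, adjusted p = 0.052) and was called in 12 of 23 alternatives, 3 of them fits that left out 1 library (adjusted p from 0.00136 to 0.209). Adjusted over that list alone, 4 were higher and 1 lower (camera adjusted p = 0.71). Of 42 clustered protocadherin genes, none was called, also adjusted over the list alone, and Pcdhgc3 was at 0.25 (adjusted p = 0.052, camera adjusted p = 0.98). Of 16 tested germline and early embryo genes, Mov10l1 alone was lower (-0.30, SE 0.08, adjusted p = 0.039, called in 1 of these fits, list alone 1 lower, camera adjusted p = 0.53). The mixed form of fry called the Zfp (adjusted p = 0.00037), heterochromatin partner (0.0098), imprinted (0.0102) and germline lists (0.0349), but not the protocadherins (0.855). It called 25 of all 34 tested lists, so such a call is not particular to these classes.

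Of 30 interferon response genes, 2 were higher, both near the detection limit. Oas3 rose from 0.149 ± 0.128 to 1.02 ± 0.527 CPM and Cxcl10 from 0.251 ± 0.043 to 1.05 ± 0.23 CPM (SD, n = 3), with log2 fold changes of 2.76 (SE 0.65, adjusted p = 0.018) and 2.05 (SE 0.50, adjusted p = 0.024). Oas3 was called in 3 and Cxcl10 in 1 of the 6 fits that left out 1 library (adjusted p up to 0.107), and Cxcl10 was not called with the Y-linked covariate (adjusted p = 0.22). Adjusted over the list alone, 4 were higher, and 25 had a positive log2 fold change. The list was called (camera adjusted p = 0.0015, adjusted p = 0.80 with an estimated correlation), but not without the library labelled CKO 2 (adjusted p = 0.0958), with the Y-linked covariate (adjusted p = 0.104) or with the stricter filter (adjusted p = 0.0755). The 4 tested Y-linked genes, with 0 called, and Xist (-2.27, SE 2.12) varied within groups as given above (Y-linked camera adjusted p = 0.15).

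The tested genes were split by mean expression into 3 bins of equal size. Higher calls made up 90.6% of the 85 calls in the lowest bin, 72.7% in the middle bin and 70.9% in the highest. The odds of a call being higher were 3.93 times larger in the lowest than in the highest bin (two-sided Fisher's exact test over genes, which are not independent replicates, p = 9.3e-05). By the same exact test, this difference was not past 0.05 without control replicate 1 (p = 0.076), control replicate 2 (p = 0.269), control replicate 3 (p = 0.0858) or CKO replicate 3 (p = 0.135). No chromosome held more or fewer calls than the rest in 44 tests, adjusted over chromosomes for higher and lower calls apart. The smallest unadjusted values by Fisher's exact test were those of higher calls on chromosome 14 (32 of 636 tested genes, odds ratio 1.73, p = 0.0063, adjusted p = 0.13), of higher calls on chromosome 4 (46 of 1050, odds ratio 1.501, p = 0.012, adjusted p = 0.13) and of lower calls on the X chromosome (13 of 591, odds ratio 2.15, p = 0.013, adjusted p = 0.29). In a principal component analysis of log2 CPM, the first component held 29.0% of the variance and separated the groups, with controls at -16.1, -31.8 and -27.6 and CKO replicates 1, 2 and 3 at 28.6, 17.0 and 29.9.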

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

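The tests with a Y-linked covariate, a ribosomal RNA covariate and without ribosomal RNA rows were chosen after the results were seen; the others were fixed before the data were examined. Over 23 alternatives with a gene test, no called gene turned its direction. Of 3345 values of 146 named genes (a gene that a filter or DESeq2 left without an adjusted p gives none), 2812 kept their side of the threshold, 441 lost a call, 92 gained one and 0 reversed; of 779 list values, 724 kept it, 42 lost a call, 13 gained one and 0 reversed. The counts of 532 higher and 188 lower genes stayed within 1.5 times under RLE, upper-quartile or no scaling, limma-voom, the legacy and non-robust fits, the stricter filter and the removal of erythroid and mitochondrially encoded genes or ribosomal RNA rows. DESeq2 called 304 genes lower. Without a filter 863 were higher and 388 lower, at an adjusted p under 0.01 247 and 34, with an absolute log2 fold change of at least 1 94 and 7, by glmTreat 118 and 5, with the Y-linked covariate 320 and 63, and with the ribosomal RNA covariate 53 and 3. The last covariate takes higher values in each CKO library than in each control, so it also takes up part of any difference between the groups. The cause was not tested beyond the narrower thresholds. Leaving out 1 library gave 255 to 1012 higher and 39 to 540 lower genes, with fewer samples in each fit.

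Trim28 passed the threshold with limma-voom (log2 fold change -0.86) and without robust estimation (-0.81). Without 1 library it ranged from -1.17 to -0.64 and was not called. It was also not called with the Y-linked covariate (-1.08, edgeR adjusted p = 0.486) or the ribosomal RNA covariate (-0.43, edgeR adjusted p = 0.897). The cause was not tested. With the replicate number as a block, 518 genes were higher and 158 lower, the Trim28 log2 fold change was -0.85 and the neuronal list was called (adjusted p = 0.047). The deviations of libraries with the same number correlated at -0.002, 0.017 and 0.001, so the numbers do not pair the libraries. Control replicate 2 and CKO replicate 2 correlated best with each other, and the other libraries correlated best with other numbers. Of the 13 called lists, 0 were called with an estimated correlation, which widens the error of correlated lists, and fry called 5. The mixed form of fry called 25 of the 34 tested lists. The excess of higher calls at low expression, 19.6 percentage points, was not past 0.05 at an adjusted p under 0.01 (13.5), with a fold minimum (42.5), by glmTreat (5.88), with the Y-linked covariate (9.04) or the ribosomal RNA covariate (2.94), where fewer genes were called, and ranged from 7.89 to 21.5 without 1 library. No chromosome passed in the main test, and 1 did with upper-quartile factors, limma-voom, the legacy fit, removal of erythroid and mitochondrially encoded genes (1) and a fold minimum (1), and 0 to 1 without 1 library; the cause was not tested. At the depth, library number and spread of these data, the simulation recovered 6% of 1.2-fold and 76% of 1.5-fold changes. This holds for genes with a mean of at least 1 CPM, and depth was not varied.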

Other observations

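The genes in this and the next paragraph were chosen after their values were seen. Ankrd1, a stretch-responsive muscle gene, was measured at 776 ± 15.6 CPM in controls and 1193 ± 64.4 CPM in CKO (SD, n = 3, log2 fold change 0.62, SE 0.05, edgeR adjusted p = 1.1e-06). Ccn2 (0.86, SE 0.11) and Ccn1 (0.65, SE 0.07) were also higher. The endothelin gene Edn1 was higher (0.82, SE 0.11, adjusted p = 0.00018) and its receptor gene Ednra was lower (-0.49, SE 0.06, adjusted p = 0.00015). The antigen presentation genes H2-K1 (0.90, SE 0.14) and H2-Ab1 (1.02, SE 0.16) were higher as well. These 7 genes were called without each library in turn, and Ankrd1 and Ccn1 also with either added covariate, whereas with the Y-linked covariate Ccn2, H2-K1 and H2-Ab1 were not called, nor with the ribosomal RNA covariate Edn1, Ednra, H2-K1 and H2-Ab1. The metallothionein gene Mt1 (1.18, SE 0.19) was higher, but not called without control replicate 1, 2 or 3 (adjusted p up to 0.0799) or with the ribosomal RNA covariate (adjusted p = 0.37).

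Several predicted genes near the start of chromosome 14 were higher. Between Gm3002 (from 3810074) and Gm3739 (to 7315049) on mm10, 12 called genes rose by 0.58 (Gm3636) to 2.17 (Gm3164) on the log2 scale. Gm3636 was at 10.7 CPM in controls and 16.0 CPM in CKO, and Gm3252 at 0.63 and 2.28 CPM. Many genes of this region are similar copies of each other, so reads can be split among them and the 12 calls are not independent. Gm8281 and Gm3591 were called without each library in turn; the other 10 each lost the call without at least 1 library, with an adjusted p of up to 0.1755, and with the ribosomal RNA covariate none of the 12 was called.

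In the part that follows, the tests of a higher share of cardiomyocytes, of a delay before lysis and of a mislabelled library were chosen after the result was seen. Those of a different share of male or female embryos rest on the Y-linked covariate, which was itself added after seeing the data. For the genes that escape X inactivation and for the library labelled CKO 2, the median met a bound set for it (54.6% of its size, above the bound of 50%; a position of 0.465, nearer 0 than 1), but not by more than its spread. The spread was the SE of the mean log2 CPM with the covariate for the escape genes, and the quartiles over genes for the library labelled CKO 2. Neither is the error of the median itself. That the bound must be exceeded by more than the spread was required after these values were seen. On the bound alone, a different share of female embryos would have been set aside and a mislabelled library would have been favoured. For a higher share of cardiomyocytes, the bound set for it (a difference of over 2 SE to the 10 most abundant sarcomere genes) was met, and on it alone the explanation would have been set aside; the comparison with all 29 sarcomere genes was added after that value was seen. The split of the 6 libraries into the labelled groups called 720 genes, and the most called by any of the other 9 splits was 0, with edgeR's quasi-likelihood test (324 to 1161 genes at an unadjusted p under 0.05). Of 10 splits, 1, the real one, gave as many, and 10 splits are too few for a share under 0.05.

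The higher level of glycolytic and hypoxia-responsive genes was weighed against 3 technical explanations. A different share of male embryos is argued against, though Y-linked expression and genotype are partly tied in these libraries. With Y-linked expression as a covariate the median log2 fold change of the list was 0.316, against 0.287 without it, and 14 of its genes were called. CKO replicate 1 had less Y-linked expression than control replicate 3 (24.9 and 31.0 CPM) but a higher mean log2 CPM of the list (7.56 and 7.28). A higher share of cardiomyocytes stays open and cannot be told apart: the mean log2 CPM of the list rose by 0.255 (SE 0.0755) more than that of the 10 most abundant sarcomere genes, but by 0.0814 (SE 0.11) more than that of all 29. A delay between dissection and lysis may contribute and stays open, since immediate-early and heat shock genes, which such a delay could induce, had a median log2 fold change of 0.318 and were called as a list (camera adjusted p = 5.0e-06, adjusted p = 0.23 with an estimated correlation). A response of the hearts to loss of TRIM28 also stays open, untested against that delay. Among the CKO libraries, the mean log2 CPM of the list was highest in CKO 2 (7.69), whose Trim28 level lay inside the control range. It was 7.56 in CKO 1 and 7.61 in CKO 3. This rests on a single library of uncertain genotype and does not decide between the explanations.

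Of 7 genes known to escape X inactivation, which were not a tested list, 3 were called lower in CKO, where 2 of the 3 libraries had almost no Xist, namely Kdm6a (-0.52), Ddx3x (-0.24) and 5530601H04Rik (-0.57), and the median of the 7 was -0.24; Kdm6a lost its call without control replicate 3 or CKO replicate 2, and the other 2 without control replicate 1, control replicate 2 or CKO replicate 3. A different share of female embryos may account for this: with Y-linked expression as a covariate the median was -0.13, 54.6% of its size, and 0 of the 7 were called. The mean log2 CPM of the 7 genes changed by -0.32 (SE 0.0713) without and by -0.18 (SE 0.0178) with the covariate, which leaves part of the fall in place. Sex and genotype are too closely tied in 6 libraries for the contributions to be separated, and they cannot be told apart for these genes.

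The library labelled CKO 2 had a Trim28 level inside the control range, and a mislabelled control library was considered. In the 1531 genes called without this library, its median position between the control mean (0) and the mean of the other CKO libraries (1) was 0.465, with quartiles of 0.213 and 0.733. Control libraries left out in the same way lay at 0.0641 to 0.144, and CKO replicates 1 and 3 at 0.939 and 1.001. These positions used other gene sets, of 301 to 539 genes, and a CKO mean that included CKO 2. They are therefore not on the same scale as 0.465. Its mean log2 CPM lay beyond the controls on the side of CKO for the glycolysis and hypoxia list (7.69, controls 7.23 to 7.30), the macrophage list (3.10, 2.73 to 2.75) and the immediate-early list (4.36, 3.81 to 3.94), and in all for 11 of the 13 called lists, whose calls include this library, but inside the control range for the ventricular (7.53, 7.38 to 7.65) and erythroid lists (3.52, 3.35 to 4.02). A control library that shared the handling of the CKO libraries, whose ribosomal RNA share it also had (0.672%), a partial loss of Trim28 and a pool of genotypes cannot be told apart from these values.

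Higher calls lay next to each other more often than chance placement gives. Neighbours were genes next to each other in the order of the genes considered along a chromosome, at any distance. Gramd1a (to 31155896) and Wtip (from 34109543) on chromosome 7 counted as a pair, for example. Among 17375 positioned genes, 46 pairs of neighbouring genes were both called higher, against a median of 16 and a maximum of 33 in 10000 permutations of the calls (p = 1e-04, the smallest they can give). Without predicted genes there were 36 pairs, against a median of 16 and a maximum of 34 in as many permutations (permutation p = 1e-04, the smallest they can give), and 1 of these pairs overlapped, against 7 of the 46. The pairs included Nppa and Nppb, Hoxa4 and Hoxa5, Col6a1 and Col6a2, Kcnj11 and Abcc8, Mt1 and Mt3, and the complement genes C1qa, C1qb and C1qc. On chromosome 4, Znf41-ps paired with Gm13212 and, without predicted genes, with Zfp992. Neighbours that share a cell type or a regulator, such as the C1q genes of macrophages, may give such an excess. The permutations account neither for these nor for expression level. Of the 5853 tested genes in the lowest expression bin 77 were called higher, and of the 5852 in the highest bin 271.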
